A study of Homo sapiens with 3 samples.

How the data were processed

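RNA of HEK293T cells was measured on 3 single-colour arrays, 1 each for an empty vector (Control), MBD3L2, and Tet2 with MBD3L2. Per the labels' protocols, total RNA was depleted of ribosomal RNA, amplified with random primers along whole transcripts, and labelled with Cy3. Per the file headers and the submitters' processing notes, the scans were read with Agilent Feature Extraction 11.0.1.1. The deposited intensity values are its processed signal per spot, which has the local background subtracted and is not normalised between arrays, together with median spot and background intensities and flags. The deposited value table of the series holds the same intensity values, not log transformed or centred, and for repeated probes the highest spot. Its column medians were 25.1, 32.4 and 23.9 for Control, MBD3L2 and Tet2+MBD3L2.

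Here, the processed signals were log2 transformed and each array was scaled to its 75th percentile over the 60639 non-control probes, since over 50% of them were well above background. The percentile stood at a signal of 139, 192 and 134 on the Control, MBD3L2 and Tet2+MBD3L2 arrays. Control spots, 60 negative probes with 600 spots, and outlier-flagged spots (42, 33 and 52 on these arrays) were left out. No spot was saturated. Spots of the same probe were averaged. A feature was counted as measured where the scanner flagged it well above background on both arrays compared. Where it was so on a single array, the fold is a bound, taken against the higher of the dim signal and the lowest signal well above background on that array. The lowest such signals were 10.4, 8.59 and 11.3. Relative to the percentile, this floor was lowest on the MBD3L2 array and highest on the Tet2+MBD3L2 array. Bounds taken against the MBD3L2 array are larger by that alone.

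Names came from the files, and RefSeq accessions were paired with symbols through a table of assembly GRCh38.p14, which was used for names only because the array was designed on an earlier build. Of 65 accessions, 63 matched. A gene with several probes took the value of the probe with the highest mean, which gave 60534 features. Probes with a manufacturer's identifier alone stayed unnamed.

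No test was run, because each group is 1 array. A feature was counted as changed from 2-fold. Before the data were examined, 30 gene lists were fixed, along with the rule for naming. Only 6 lists had a named member on the array (HOX genes, ribosomal proteins, housekeeping genes, glycolysis and hypoxia, oxidative phosphorylation, and nuclear noncoding RNAs), and the other lists, including markers of other cell types, were not analysed here. Lists with at least 3 measured members were set against 10000 random lists matched on mean signal in 20 bins. The naming rule took, in each comparison, the 8 highest and 8 lowest named features. These had to be at least 2-fold changed and at least 1.5-fold with normexp and with quantile normalization. Their brighter array had to reach its median detected signal, and no other probe of the gene could go at least 1.5-fold the other way. It added the 3 largest bounds each way and up to 4 members of each list. Before the limit of 8 each way, 17, 30 and 11 features met the rule in the 3 comparisons, of which 1 had only a clone-type name and was not printed. Some features that the rule selects are not reported here.

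Alternatives were normexp background correction (offset 50, on the median signal because no mean signal was given in these files), quantile normalization, cyclic loess, no scaling, median centring, the percentile over probes detected on all arrays, no filter and a stricter filter on dim probes, the median over a gene's probes, leaving out saturated probes, the series value table, and thresholds of 1.5-fold and 3-fold. Changes of signal and counts were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures with matplotlib 3.10.9, and the normalizations with limma 3.58.1 in R 4.3.3.

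The calling step was tested on simulated arrays of 37919 features with a noise SD of 0.1 and 200 changed features. For MBD3L2 over Control, all 25 features raised 3-fold and all 25 lowered 3-fold were called. Of those changed exactly 2-fold, 12 of 25 raised and 11 of 25 lowered were called, and 0 of 37719 unchanged features were called. The simulated noise was smaller than the spread between different probes of a gene (SD of change 0.41 to 0.56), and detection was the same on both arrays. The last count was therefore fixed by the setting and does not give the rate of false calls on the real arrays.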

Results

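The series asked which transcripts differ in HEK293T cells when MBD3L2 is overproduced alone or together with Tet2. HEK293T is a human embryonic kidney line that carries the SV40 large T antigen and takes up plasmids readily. Tet2 is a dioxygenase that oxidises 5-methylcytosine in DNA, and MBD3L2 is a relative of the methyl-CpG-binding domain protein MBD3 that lacks the domain itself. Cells received an empty vector (Control), MBD3L2, or Tet2 with MBD3L2 (Tet2+MBD3L2), and each condition was measured on 1 single-colour Agilent array. A condition with Tet2 alone was not analysed here. With 1 array per group, no difference has a replicate check, so changes are described by size and no test was run. The number of arrays limits the precision, and the errors given for repeated spots are technical and leave out the spread between cultures.

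Each array held 60639 non-control probes. Of these, 37919 (62.5%) were well above background on the Control array, 42035 (69.3%) on the MBD3L2 array and 37075 (61.1%) on the Tet2+MBD3L2 array. Only 1366 probes carry a name here, and the other 59273 carry the manufacturer's identifier alone. The named probes cover HOX exons (93) and introns (53), features named nc-HOX after a HOX gene (212, read here as noncoding RNAs of the HOX clusters), ultraconserved regions (962, named uc with a number and a strand sign), other noncoding RNAs (25), 20 reference genes and p53 mRNA. No probe could be paired by name with TET2, MBD3L2 or its paralogues, so the level of the transfected genes was not analysed here and the labels have no check from them. Repeated spots of the reference genes differed by a pooled SD of 0.10 on the log2 scale. Most of these genes are bright. The dimmest, GRM4 (signal 17.4 on the Control array), had an SD of 0.31, 0.21 and 0.32 on the Control, MBD3L2 and Tet2+MBD3L2 arrays. The pooled value may therefore understate the spread of dim features. Different probes of the same gene spread more widely, with a pooled SD of 0.41 for the MBD3L2 change and 0.56 for the Tet2+MBD3L2 change.

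The first comparison asked what MBD3L2 alone went with. HOX genes, which encode the transcription factors that set position along the body axis, were mostly lower on the MBD3L2 array than on the Control array under the scaling used. All 38 named HOX genes were measured, and 33 of them lay below the median change of all measured features. Their median log2 change was -0.43, or -0.20 relative to that median, and stood at percentile 4.7 among 10000 random lists of like signal, whose own median was -0.31. The 20 reference genes lay at -0.24 relative to all features, as low as the HOX genes. Without scaling the median over Control turned to 0.04. HOXA3 was the only one of these 38 at least 2-fold lower, by 2.06-fold in exon 3, and 1 HOX exon feature with no matched symbol was at least 2-fold lower too. The other measured exon probes of HOXA3 changed by -0.52 and -0.46. The log2 change of -1.04 in exon 3 fell short of 2-fold with normexp (-0.82), cyclic loess (-0.97), median centring (-0.94), no scaling (-0.58) and the median over its probes (-0.52). HOXB8 (log2 change -0.78), HOXC8 (-0.78) and HOXD4 (-0.72) followed, each read in exon 2, and their other measured probes changed less, between -0.23 (HOXD4) and -0.05 (HOXB8). The HOX shift relative to all features was smaller with normexp (-0.07), cyclic loess (-0.09), quantile normalization (-0.10) and the median over a gene's probes (-0.08).

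The nc-HOX features were also lower on the MBD3L2 array under this scaling. Of 159 measured, 9 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 change of -0.46, or -0.24 relative to all features, and without scaling the median turned to 0.005. The lowest that met the fixed rule for naming were nc-HOXD8-19 (2.24-fold lower) and nc-HOXB4-175 (2.14-fold lower). Neither reached 2-fold with normexp (-0.78 and -0.65 on the log2 scale) or without scaling (-0.70 and -0.63), nor did nc-HOXB4-175 with median centring (-0.99). HOTAIRM1, a long noncoding RNA from the HOXA cluster, changed by -0.45, which turned to 0.02 without scaling. All named noncoding RNAs (159 of 175 measured were nc-HOX) and all 62 named protein-coding features, mostly HOX and reference genes, had nearly equal medians (-0.44 and -0.46), so this is not a comparison of the classes at large. That difference of 0.02 turned to -0.20 with quantile normalization and -0.16 with cyclic loess.

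Ultraconserved regions went both ways, with 12 of 333 measured strands at least 2-fold higher on the MBD3L2 array and 18 at least 2-fold lower. Among the higher ones, uc.392+ was 8.35-fold, uc.267+ 3.02-fold, uc.50- 2.59-fold and uc.203+ 2.36-fold brighter. The minus strands uc.418- and uc.420- were 2.24-fold and 2.21-fold higher, uc.330+ 2.24-fold and uc.12- 2.12-fold. Among the lower ones were uc.460- (2.93-fold), uc.418+ (2.50-fold), uc.258- (2.38-fold), uc.28- (2.09-fold) and uc.18- (2.01-fold). With normexp uc.392+ changed by 1.96 on the log2 scale in place of 3.06. Under 2-fold then were uc.267+ (0.96), uc.203+ (0.84), uc.330+ (0.97), uc.12- (0.74), uc.418+ (-0.91), uc.258- (-0.78) and uc.28- (-0.63). Without scaling, uc.418+ (-0.86), uc.258- (-0.78), uc.28- (-0.59) and uc.18- (-0.54) were under 2-fold. So were uc.28- (-0.97) and uc.18- (-0.88) with cyclic loess, both with median centring (-0.96 and -0.90), and uc.18- (-0.92) with quantile normalization. The signals of uc.66-, uc.44- and uc.243- were not well above background on the MBD3L2 array, which put them at least 8.81-fold, 5.54-fold and 5.04-fold lower. In the other direction, uc.210+, uc.213- and uc.441- were not well above background on the Control array and were at least 2.37-fold, 1.89-fold and 1.77-fold higher with MBD3L2. The spot of uc.210+ was at least 8-fold brighter on the MBD3L2 array alone, and that of uc.243- on the Control array alone. A stray spot is not excluded for either. With normexp the bounds of uc.66-, uc.44- and uc.243- shrank from 3.14, 2.47 and 2.33 on the log2 scale to 1.26, 0.92 and 0.93. Those of uc.210+ (1.24) and uc.213- (0.92) shrank to 0.27 and 0.05, and that of uc.441- (0.82) turned to -0.07.

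The reference genes showed how far the scaling sets these directions. GAPDH, a glycolytic enzyme, was 1.85-fold higher on the MBD3L2 array (log2 change 0.89 ± 0.03, SE over repeated spots), whereas 17 of the 20 reference genes had a negative change. ACTB, which encodes beta-actin, changed by -0.60. The ribosomal protein genes RPS18, RPLP1 and RPL10 changed by -0.63, -0.58 and -0.49, and the respiratory chain gene COX4I1 changed by -0.46. PGK1, also glycolytic, changed by 0.27. Without scaling the median over the 20 genes was -0.002 in place of -0.47. With quantile normalization RPS18 and RPLP1 stood at -0.09 and -0.04 and COX4I1 at 0.03, so the direction of COX4I1 turned and that of GAPDH (1.18) did not. COX4I1 (0.003) also turned without scaling. The median of the 3 ribosomal protein genes lay at percentile 11.4 of random lists, and that of the 4 measured housekeeping genes (-0.07) at percentile 88.9. The glycolysis and hypoxia list, with GAPDH and PGK1 alone, had a median of 0.58.

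Over all features, 37068 were measured on both arrays. Of these, 2026 were at least 2-fold higher with MBD3L2 and 942 at least 2-fold lower, so that 68.3% of the changed features were higher. The median change was -0.23 on the log2 scale. No scaling moved it by 0.47, cyclic loess by 0.12 and median centring by 0.10, and the share that was higher became 97.5%, 82.3% and 82.1%. Quantile normalization gave 78.7% and normexp 91.0%. The share was 48.1% with no filter on dim probes and 86.6% with the stricter filter. At 1.5-fold the majority turned, with 4834 higher and 6186 lower. Of these 2 arrays, another 4890 features were well above background on MBD3L2 alone and 786 on Control alone. By the bounds, 299 of the former were at least 2-fold higher and 665 of the latter at least 2-fold lower. After scaling, the lowest signal well above background was lower on the MBD3L2 array (8.59 at a percentile of 192) than on the Control array (10.4 at 139). Features found on Control alone therefore passed the bound more easily. Neither the detection counts nor the bounds thus give the direction of change.

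The second comparison set Tet2+MBD3L2 against Control. HOX genes were again lower as a group, and HOXD1 stood apart from them. The comparison shares the Control array with the first, so the lower HOX signal is not an independent repeat. Of 38 HOX genes, 34 lay below the median change of all features. Their median log2 change was -0.42, or -0.32 relative to all features, at percentile 0.25 of the random lists (random median -0.18), and it stayed between -0.19 and -0.41 under the other settings. HOXA3 was 2.35-fold lower in exon 3, but its exon 4 probe changed by 0.14 and the median over its probes was -0.55. HOXA11 (log2 change -0.96) was also low, in exon 1, and its other measured probe changed by -0.26. HOXD1 was 4.90-fold higher in exon 2, a single spot, while its intron probe changed by -0.35 and its exon 1 probe was not well above background on any array. The median over its measured probes was 0.97 on the log2 scale, under 2-fold.

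**Figure D1:**
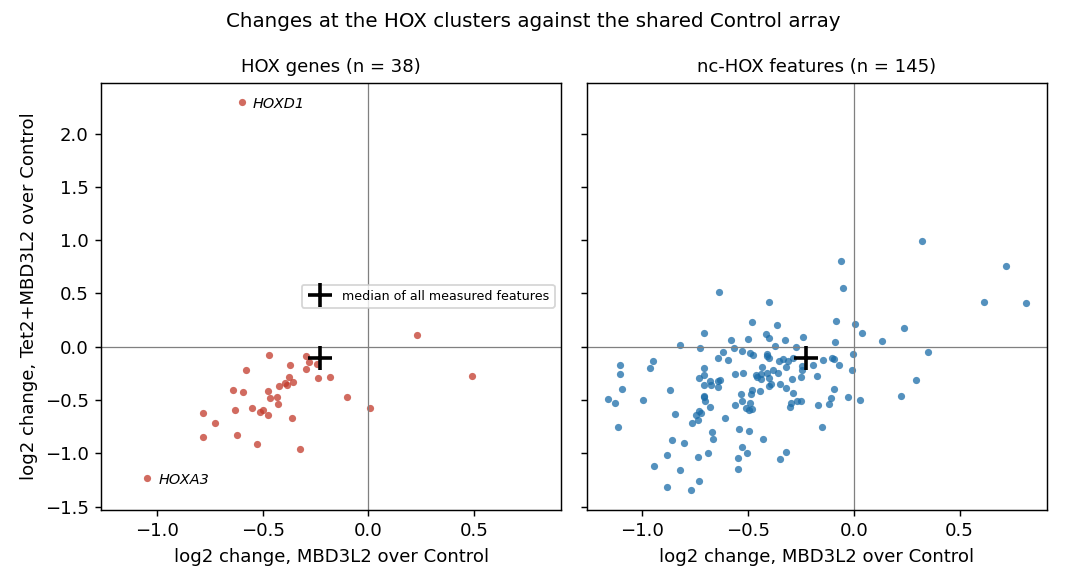
Log2 change over the shared Control array for each HOX gene (left, n = 38) and each nc-HOX feature (right, n = 145) measured on all arrays, with MBD3L2 on the x axis and Tet2+MBD3L2 on the y axis. Each point is a feature, the cross marks the medians of all measured features (-0.23 and -0.10), and 34 HOX genes and 116 nc-HOX features have negative changes on both axes, of which 30 and 91 lie below the medians of all features on both.

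Among the 146 measured nc-HOX features, 10 were at least 2-fold lower with Tet2+MBD3L2 and 0 were at least 2-fold higher. Their median log2 change was -0.30, or -0.20 relative to all features. By cluster, the HOXB features had the lowest median (-0.42, with 5 of 33 at least 2-fold lower), and the HOXA features the highest (-0.19, with 0 of 31). HOTAIRM1 changed by -0.37. The same noncoding and protein-coding sets again had like medians (-0.32 and -0.29). nc-HOXB9-194 was well above background on the Tet2+MBD3L2 array alone and at least 3.92-fold higher there. It is among the spots at least 8-fold brighter on that array alone, and a stray spot is not excluded.

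Ultraconserved regions were more often lower than higher in this comparison, with 29 of 296 measured strands (9.80%) at least 2-fold lower and 4 (1.35%) at least 2-fold higher. Over all features the shares were 3.92% lower and 5.15% higher. The median log2 change of the class, -0.27, became -0.09 with normexp (all features -0.05). With no filter on dim probes it turned to 0.02 (all features -0.01). The lowest that met the naming rule were uc.258- (4.40-fold), uc.460- (3.73-fold), uc.209+ (3.54-fold), uc.418+ (3.43-fold) and uc.30+ (3.24-fold), followed by uc.174- (3.08-fold), uc.193+ (3.03-fold) and uc.18- (2.72-fold). With normexp uc.258- and uc.193+ changed by -0.85 and -0.77 on the log2 scale, under 2-fold, and uc.460- (-1.89) was the lowest of these. The higher ones that met the naming rule were uc.267+ (2.69-fold, but 0.80 on the log2 scale and so under 2-fold with normexp) and uc.50- (2.29-fold). uc.66-, uc.255- and uc.44- were not well above background with Tet2+MBD3L2 and were at least 4.68-fold, 2.99-fold and 2.94-fold lower. The larger bounds of uc.66- and uc.44- with MBD3L2 come from the lower scaled floor of that array alone. uc.241+ and uc.53- were well above background there and not on the Control array, at least 4.53-fold and 2.58-fold higher. With normexp no bound of uc.66-, uc.255-, uc.44-, uc.241+, uc.53- or nc-HOXB9-194 in this comparison exceeded 0.79 on the log2 scale. Of the spots dim on both other arrays, 0.921% were at least 8-fold brighter on this array alone, and 0.885% of dim control spots were so too.

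GAPDH was 2.20-fold higher with Tet2+MBD3L2 (log2 change 1.14 ± 0.03, SE over repeated spots). No other reference gene changed by more than 0.11 upwards, and the lowest, RPL10, changed by -0.60. PGK1 changed by -0.36, ACTB by -0.12, RPS18 by -0.10, RPLP1 by -0.04 and COX4I1 by -0.07. With cyclic loess the direction turned for ACTB (0.08), RPS18 (0.10), RPLP1 (0.17) and COX4I1 (0.13). With quantile normalization it turned for RPLP1 (0.01) and COX4I1 (0.05). The ribosomal protein and housekeeping lists had medians of -0.10 and -0.09, at percentiles 54.6 and 61.0 of random lists, and the median of GAPDH and PGK1 was 0.39.

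**Figure D2:**
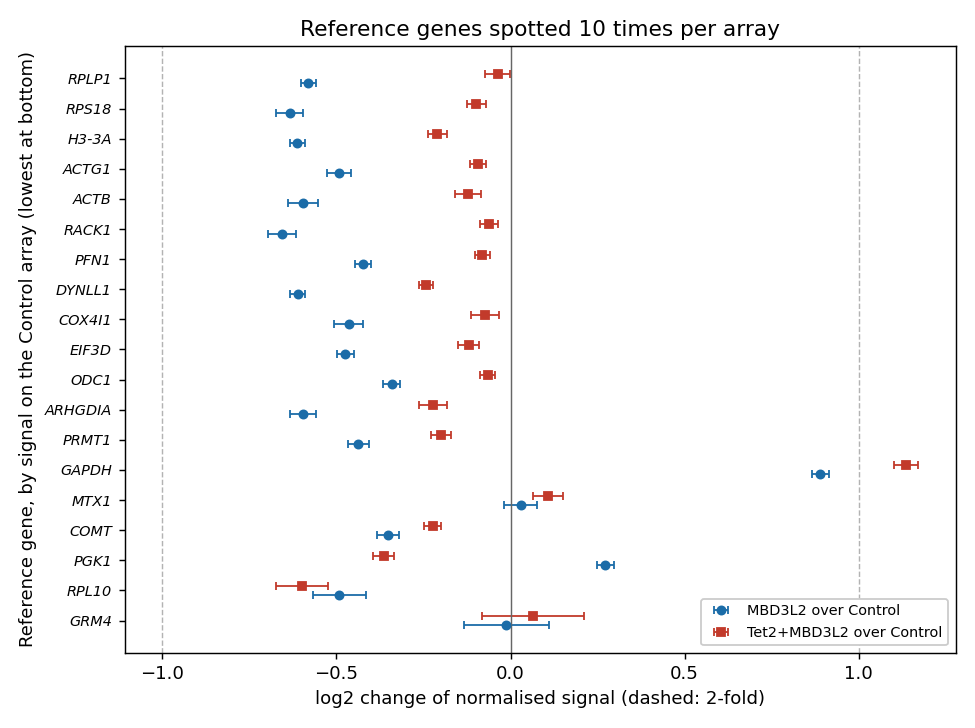
Log2 change over Control of 19 of the 20 reference genes spotted 10 times on each array, ordered by signal on the Control array, for MBD3L2 (circles) and Tet2+MBD3L2 (squares). Bars are standard errors from repeated spots and dashed lines mark 2-fold. GAPDH lies at 0.89 and 1.14, and the other genes shown lie between -0.66 and 0.27 with MBD3L2 and between -0.60 and 0.11 with Tet2+MBD3L2.

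Over all features, 34905 were measured on both arrays, with 1797 at least 2-fold higher with Tet2+MBD3L2 and 1367 at least 2-fold lower. The higher ones made up 56.8% of these, and 71.5% with cyclic loess, which moved the median change of -0.10 by 0.11. The majority turned without scaling (1566 higher and 1637 lower, 48.9%) and with normexp (599 and 605, 49.8%), and also at 1.5-fold (4501 and 5156). Of these 2 arrays, a further 2114 features were well above background with Tet2+MBD3L2 alone and 2949 with Control alone. By the bounds, 633 of the former were at least 2-fold higher and 340 of the latter at least 2-fold lower. The scaled floor was slightly higher on the Tet2+MBD3L2 array than on the Control array, which favours the former.

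The third comparison, Tet2+MBD3L2 over MBD3L2, bears on what the addition of Tet2 went with. HOXD1 exon 2 was 7.41-fold higher with Tet2 added, and its intron probe changed by -0.14, so that the median over its measured probes was 1.37 on the log2 scale. The median log2 change of the 38 HOX genes was -0.003, or -0.05 relative to all features, at percentile 30.2 of random lists, and normexp background correction moved the latter to -0.23. Without scaling the former was -0.52. HOXB9 (log2 change -0.76), HOXA11 (-0.64) and HOXA2 (-0.58) were the lowest of the named examples. The other measured probe of HOXA11 changed by -0.16, and those of HOXA2 by -0.24 and 0.21. Of 147 measured nc-HOX features, 2 were at least 2-fold higher and 0 lower, with a median of 0.11 that turned to -0.41 without scaling.

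Ultraconserved regions at least 2-fold lower with Tet2 added numbered 13 of 304 measured strands, and 4 were at least 2-fold higher. uc.392+ was 4.92-fold, uc.184- 3.72-fold, uc.203+ 2.99-fold and uc.63- 2.84-fold lower. uc.392+ and uc.203+, and uc.210+ below, were also higher on the MBD3L2 array than on the Control array. The same MBD3L2 reading enters both comparisons, so these are not separate observations. uc.193- (2.61-fold), uc.209+ (2.32-fold), uc.208+ (2.28-fold) and uc.101- (2.22-fold) were lower as well. uc.110- was 2.59-fold higher (0.85 on the log2 scale and so under 2-fold without scaling). Against the MBD3L2 array, uc.241+, nc-HOXB9-194 and uc.53- were at least 7.56-fold, 6.55-fold and 4.31-fold higher, all well above background on the Tet2+MBD3L2 array alone. All are among the spots at least 8-fold brighter on that array alone, and a stray spot is not excluded for any of them. Their bounds exceed those over Control only because the scaled floor of the MBD3L2 array is lower. uc.255-, uc.376- and uc.210+, the last with a stray spot not excluded, were at least 2.88-fold, 2.77-fold and 2.10-fold lower. With normexp these bounds shrank to 0.28, 0.25 and 0.15 on the log2 scale, and those of uc.241+, nc-HOXB9-194 and uc.53- to 1.1, 1.03 and 0.87. uc.184- then changed by -0.72, under 2-fold. PGK1 changed by -0.64 and GAPDH by 0.25, the latter turning to -0.27 without scaling. RPLP1, RPS18, RPL10, COX4I1 and ACTB changed by 0.54, 0.54, -0.11, 0.39 and 0.47. Without scaling the direction turned for COX4I1 (-0.13) and ACTB (-0.05), and with normexp for RPL10 (0.15). Without scaling, the median change of the 20 reference genes was -0.17 in place of 0.35. HOTAIRM1 changed by 0.08, which turned to -0.10 with normexp, -0.44 without scaling, -0.03 with cyclic loess and -0.006 with median centring. The ribosomal protein and housekeeping lists had medians of 0.54 and 0.30, at percentiles 97.1 and 78.5 of random lists, and the median of GAPDH and PGK1 was -0.20. Relative to all features, the ribosomal protein list fell from 0.48 to 0.030 with quantile normalization, and the housekeeping list turned to -0.040.

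Of 36170 features measured on both arrays, 934 were at least 2-fold higher with Tet2 added and 549 lower. The higher share was 63.0%, against 7.65% without scaling, which moved the median of 0.05 by -0.52, 50.6% with median centring and 47.3% with normexp. The stricter filter on dim probes left 258 higher and 388 lower. Of these 2 arrays, a further 849 features were well above background with Tet2+MBD3L2 alone and 5788 with MBD3L2 alone. By the bounds, 807 of the former were at least 2-fold higher and 146 of the latter at least 2-fold lower. This split is largely set by the floors. After scaling, the lowest signal well above background was lower on the MBD3L2 array (8.59 at a percentile of 192) than on the Tet2+MBD3L2 array (11.3 at 134). The former therefore passed more easily, and the 2 counts do not give a direction of change.

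The 2 changes against Control were set against each other across features. Over 34773 features well above background on all arrays, the correlation was 0.67 and the covariance 0.23. These are values across features of the same arrays, which are not independent replicates. Both changes subtract the same Control array, and simulated equal noise on unchanged arrays gave a correlation of 0.49 and, at the spread of repeated spots, a covariance of 0.01. Arrays of unequal spread give other values. If the conditions shared no effect, the variance private to an array would be 0.23 for Control, which is the covariance itself, 0.10 for MBD3L2 and 0.12 for Tet2+MBD3L2, and the correlation would be the one observed. Among features at least 2-fold higher, 1001 were shared, where independent lists would share 103, and among those lower 218 were shared, where independent lists would share 28.2. These overlaps share the Control array too. It could not be split, so a shared effect was not separated from values peculiar to that array.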

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

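No paired analysis was possible because each group is 1 array and no test was run. Leaving out a replicate was not possible for the same reason. A log2 value was taken as unmoved within 0.14, the spread of a difference of single spots, a count within 1.5 times, and the covariance within the 95% bootstrap interval over features (0.22 to 0.23), which covers no spread between cultures. The limit of 0.14 comes from reference genes, most of them bright, and may be narrow for dim features. The level of TET2 and MBD3L2 gave no value under any setting. Leaving out saturated probes removed nothing. Signal over background limits the dim features, since 6.33% to 9.0% of negative-probe spots also passed as well above background. That rate was uneven, as the probes Negative010 and Negative059 passed in every spot on each array and most other negative probes in none. The cause of the shifts below was not tested, except that thresholds and filters change counts by construction.

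At 1.5-fold the counts higher and lower were 4834 and 6186 for MBD3L2 over Control, 4501 and 5156 for Tet2+MBD3L2 over Control, and 3328 and 2662 for Tet2+MBD3L2 over MBD3L2. At 3-fold they were 275 and 97, 317 and 136, and 294 and 63. With no filter on dim probes they were 4223 and 4549, 5019 and 4779, and 4480 and 2959. With normexp they fell to 942 and 93, 599 and 605, and 191 and 213. Without scaling, MBD3L2 over Control gave 5301 and 137, and Tet2+MBD3L2 over MBD3L2 gave 324 and 3911. The count lower for MBD3L2 over Control became 625 with quantile normalization, 564 with cyclic loess, 568 with median centring and 262 with the stricter filter. The stricter filter gave 258 higher for Tet2+MBD3L2 over MBD3L2. The covariance of the changes was 0.11 with normexp, 0.30 with no filter and 0.28 with the stricter filter.

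Relative to all features, the HOX median was negative in all 3 comparisons and all 11 alternatives, of which 4 could not change it (no scaling, median centring and the percentile over detected probes cancel, and no probe was saturated). It moved for Tet2+MBD3L2 over MBD3L2 with normexp, to -0.23. The 3 ribosomal protein genes reversed for MBD3L2 over Control with quantile normalization (0.042), and stood at -0.21 with normexp and -0.080 with cyclic loess. For Tet2+MBD3L2 over MBD3L2 their values were 0.25 with normexp, 0.030 with quantile normalization and 0.25 with cyclic loess. The 4 housekeeping genes moved to 0.33 for MBD3L2 over Control with quantile normalization. For Tet2+MBD3L2 over MBD3L2 they reversed with quantile normalization (-0.040) and stood at 0.046 with normexp and 0.083 with cyclic loess. Noncoding minus protein-coding medians became -0.20 with quantile normalization and -0.16 with cyclic loess for MBD3L2 over Control, and 0.13 with normexp for Tet2+MBD3L2 over Control. Of 39 named changes of at least 2-fold, 25 stayed at least 2-fold with normexp and all kept their sign in each alternative, but the naming rule had picked features that keep their direction with normexp and quantile normalization.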

Other observations

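All tests below were chosen only after the result was seen. The features singled out here that fall outside the naming rule (HOXA9, HOXB6, uc.50+ and probes by identifier) were chosen after their values were seen.

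The strands of an ultraconserved region showed little common change. In MBD3L2 over Control, 77 regions had both strands measured, and their changes had a correlation of -0.22 across regions, which are not independent replicates. In uc.418 the minus strand was higher (log2 change 1.16) and the plus strand lower (-1.32). In uc.50 the changes were 1.37 for the minus and -1.04 for the plus strand. Both cases depend on the scaling. Leaving it out raises each change in this comparison by 0.47, which takes both plus strands under 2-fold. With normexp uc.418+ changed by -0.91. No region had its strands at least 2-fold apart from Control in opposite directions in Tet2+MBD3L2 over Control, where 64 were measured, 1 had both strands at least 2-fold changed the same way, and the correlation was -0.18. In Tet2+MBD3L2 over MBD3L2 the correlation was 0.17 over 68 regions.

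Probes within a HOX gene also parted. HOXA9 exon 1, a dim probe, changed by 1.48 with MBD3L2 and 1.25 with Tet2+MBD3L2, while its bright exon 2 probe changed by -0.46 and -0.48. HOXB6 exon 1 was well above background on the Tet2+MBD3L2 array alone, while exon 4 changed by -0.42 there. This exon 1 probe is among the spots at least 8-fold brighter on that array alone, and a stray spot is not excluded. HOXA3 holds a probe in intron 2 that was well above background on the MBD3L2 array alone, at a scaled log2 signal of 2.41, against -4.60 and -3.86 on the Control and Tet2+MBD3L2 arrays. The 17 non-control spots bright on the MBD3L2 array alone also lay near each other, at a median of 6.46 spot pitches against 10.98 for the lowest random draw, so a stray spot is not excluded for this probe. ASHG19A3A048976 had a signal of 143198 on the Control array and 15.9 and 11.3 on the MBD3L2 and Tet2+MBD3L2 arrays, and a stray spot is not excluded here either. ASHG19A3A007254 was not well above background on the Control array (5.40) and read 464 and 150 on the MBD3L2 and Tet2+MBD3L2 arrays.

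Features bright on the Tet2+MBD3L2 array alone may largely be stray spots. Of 17806 non-control spots dim on both other arrays, 164 (0.921%) were at least 8-fold brighter here, against 40 on the Control and 17 on the MBD3L2 array. Among dim control spots, 13 of 1469 (negative, spike-in and other controls, 0.885%, exact 95% interval 0.47% to 1.51%) were so too. The bright spots also lay near each other, at a median of 4.21 spot pitches from the nearest like spot, below the lowest of 1000 random draws (6.83). Both values are consistent with marks on the array surface, and the interval of the control spots is wide enough that transcripts switched on by Tet2 with MBD3L2 cannot be told apart from them for part of these features.

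HOXD1 exon 2 was 4.90-fold brighter with Tet2+MBD3L2 than with Control. The 3 other measured probes at the locus (the intron probe, nc-HOXD1-46 and nc-HOXD1-48) did not rise with it, with a median change of -0.44 and a highest of -0.35. The nc-HOXD1 features are read here as separate noncoding RNAs and need not follow the gene. The intron probe was dim, at a scaled log2 signal of -2.83 on the Control and -3.17 on the Tet2+MBD3L2 array. Higher transcription of HOXD1 is therefore not excluded. A mark at this spot stays open. Of all spots, 39.3% lie closer to a spot bright on this array alone, which places it near no such group, but a single mark could stand apart and the probe was spotted once. A higher level of the spliced transcript alone was not tested.

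GAPDH was brighter on the MBD3L2 and Tet2+MBD3L2 arrays than on the Control array, by 0.89 and 1.14 on the log2 scale. Spread between repeated spots was argued against, with both changes at 33.4 standard errors or more. Scaling was argued against, as the lowest change over 7 scalings and both arrays was 0.89. A response that changes with signal was argued against too, since MTX1 and PRMT1, next below and above GAPDH in signal, changed by -0.44 to 0.11. A higher GAPDH level in the MBD3L2 and Tet2+MBD3L2 cultures than in the empty vector culture, by condition or by chance, stays open as a hypothesis, because each condition is 1 array and GAPDH has 1 named probe.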
